A study of Mus musculus with 12 samples.

How the data were processed

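Gene expression was measured on Illumina mouse bead arrays in 12 samples, 3 each of embryonic stem cells (ESC), embryonic fibroblasts (MEF) and induced pluripotent stem cells made with 4 factors (iPS4F) or with 6 factors (iPS6F). Per the labels, RNA was amplified into biotin-labelled cRNA. Samples were grouped by their titles. The labels number the arrays of each group 1 to 3 but do not say whether they came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

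The deposited table gives the intensity of each probe, per the file headers, and its values were neither normalized nor background-subtracted, with the lowest at 64.1 and the highest at 21025. Beside each intensity the deposited table holds a detection p-value, which fell as the intensity rose. A further table of the authors holds log2 values of the same arrays. All 12 columns of that log2 table shared a median of 1.16, and each column ranked the probes of its array as the intensity did (Spearman correlation 1). At each rank the columns differed by at most 0.000817, so the columns share one distribution, as quantile normalization gives. Their lowest value was -0.4952, where log2 of the lowest intensity would be near 6, so a background was also removed or the scale shifted. The order and settings of those steps are not given in the sources used here. Per the submitters' processing notes, BeadStudio 3.2, RMA and lumi were used, with no role stated for each.

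The intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected the background with a normal-exponential model, taking the background from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. The offset keeps dim probes off the log scale's steep end, so folds of weakly expressed genes are understated. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none here. No symbol was updated through its gene identifier. Probes with several symbols or none were left out of the gene tests. Those names can be old. A probe was kept if its detection p was under 0.05 on all 3 arrays of at least 1 group, which kept 17563 probes, 15294 of them with a symbol. Each gene was represented by its kept probe of highest mean, giving 10096 genes, of which 3648 had more than 1 kept probe.

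One linear model with a mean for each of the 4 groups was fitted to all 12 arrays, with lmFit and eBayes, so that the groups shared an estimate of the spread. The 6 differences between groups were tested, with Benjamini-Hochberg adjustment within each difference and a threshold of 0.05. A further count also asked for a difference of at least 2-fold. Levels are mean log2 intensities ± SD over 3 arrays, and differences are log2 ± standard error (SE). A gene undetected on every array of a group has only a bound there. For it the text gives "at least N-fold", the brighter group's mean over the mean, per array, of the higher of the gene's own value and the lowest value of a detected probe.

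Before the data were examined, 26 gene lists with 587 entries were fixed, of which 40 entries had no named probe. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01, which compares the list with the other genes, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way, were alternatives. A list is said to be called where camera with the preset correlation passed it, and fry passed many lists that camera did not. Named genes followed a rule fixed at the same time. Part a took, per comparison, the 8 genes of highest and the 8 of lowest log2 difference among those past the threshold, with every array of the higher group above every array of the lower, detected on all arrays of the higher group and carrying a proper gene name. Part b took the 6 factors and the measured BAF subunits. Part c took up to 4 members of largest change per list past the threshold, or 2 where fewer than 2 passed. Other genes are said to have been chosen after their values were seen.

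The distance of an iPS array to ESC was the root mean square, over the 10096 genes, of its log2 difference from the mean of the ESC arrays. Its share of the MEF to ESC difference was the slope of the array's difference from the MEF mean on the ESC mean's difference from it, over 3895 genes. Both were compared by a two-sided exact permutation test of 3 arrays against 3, whose smallest p is 0.1. The correlation and covariance of the iPS differences from ESC were set beside 100 simulations of unchanged iPS groups against the same ESC arrays. A mouse gene table (GRCm38.p6) gave the chromosome and order of genes. Chromosome medians, and shares among the genes at least 2-fold apart from ESC in both iPS lines, were set beside 10000 random lists. These had the same size and were matched on mean expression. The medians of the fixed lists were not set beside random lists.

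The fit was tested on simulated data with planted differences between iPS6F and iPS4F. It called 58.2% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 5 false calls among 173. Alternatives covered the background correction, the normalization, the authors' log2 values, the detection filter, the probe rule, the model, the replicate number as a block and each array left out. Removing the genes of chromosome 8 and leaving out arrays in the list tests were added after the data were seen. The number of arrays, 3 per group, limits the precision.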

Results

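Transcripts were measured on Illumina mouse bead arrays in 4 kinds of cells, with 3 arrays of each. ESC were embryonic stem cells of the OG2 mouse line, labelled as a mix of female and male. MEF were embryonic fibroblasts of the same line, labelled male. The iPS4F cells had been reprogrammed with Oct4 (Pou5f1), Sox2, Klf4 and c-Myc, and the iPS6F cells with those 4 factors plus Brg1 (Smarca4) and Baf155 (Smarcc1). Brg1 and Baf155 are subunits of the BAF complex, which moves nucleosomes with energy from ATP. The mean raw intensity ran from 139 on ESC array 2 to 237 on iPS4F array 1, and the number of detected probes from 14107 to 17741 on the same arrays, of 45281.

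Across genes, the arrays of one group correlated at 0.990 to 0.995. The median correlation between iPS4F and iPS6F arrays was 0.990, that of ESC with iPS4F 0.964 and that of ESC with iPS6F 0.957. MEF stood apart, with median correlations of 0.706 to ESC, 0.693 to iPS4F and 0.684 to iPS6F. Genes are not independent replicates, so these values carry no test.

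The 6 reprogramming factors were examined before any other gene. Pou5f1, the core pluripotency factor, rose from 4.58 ± 0.08 in MEF to 10.34 ± 0.13 in ESC, 11.35 ± 0.16 in iPS4F and 11.74 ± 0.10 in iPS6F (log2 intensity, SD, n = 3). Sox2, its partner on DNA, stood at 4.35 ± 0.15 in MEF, 6.80 ± 0.36 in ESC, 8.39 ± 0.26 in iPS4F and 8.48 ± 0.09 in iPS6F. Klf4 was lower in iPS4F (5.92 ± 0.26) and iPS6F (6.27 ± 0.20) than in ESC (7.08 ± 0.19), and median scaling ended both of these calls (log2 differences -0.49 and -0.48). The Myc probe lay near the floor in all groups and was detected on the 3 MEF arrays and on no ESC or iPS array. Smarca4 stood at 5.86 ± 0.07 in iPS4F and 6.06 ± 0.13 in iPS6F, a log2 difference of 0.20 ± 0.11 (SE, adjusted p = 0.513), against 6.67 ± 0.10 in ESC. Smarcc1 stood at 8.19 ± 0.24 in iPS4F and 8.45 ± 0.15 in iPS6F, a log2 difference of 0.25 ± 0.17 (adjusted p = 0.593). The sources used here do not say whether a delivered factor would hold the target of its probe, so these levels check neither delivery nor later loss of the added copies.

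**Figure D1:**
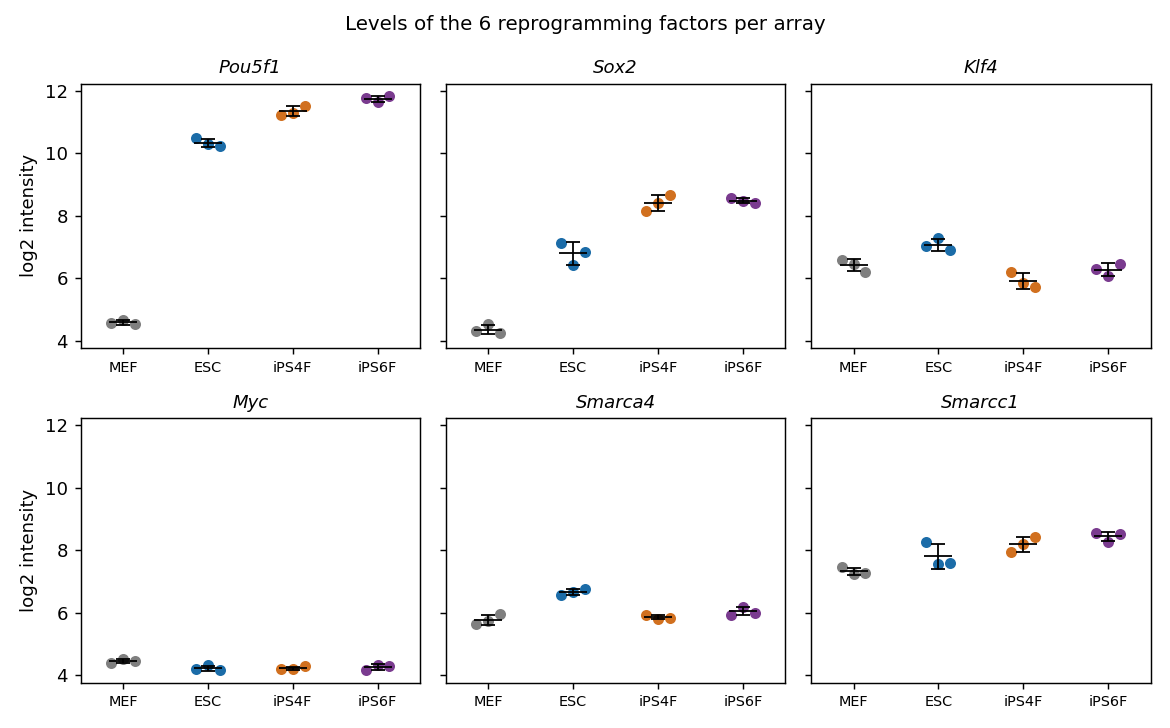
Log2 intensity of each of the 6 factors on each array, by group (points, 3 arrays per group), with the group mean and SD (black bars). Pou5f1 and Sox2 were lowest in MEF and highest in the iPS groups, and the iPS6F and iPS4F arrays of Smarca4 lay below those of ESC.

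ESC were compared with MEF to describe the gap between the starting cells and the pluripotent reference. Dppa5a, a marker of pluripotent cells, was 704-fold higher in ESC (log2 difference 9.46 ± 0.11). Upp1, which splits uridine, was at least 277-fold higher, Wfdc2 at least 190.0-fold, Dnmt3l, a partner of the enzymes that set new DNA methylation, 209-fold, and Esrrb, a nuclear receptor of the pluripotency network, at least 107-fold. In the other direction, Ptn, a secreted growth factor, was at least 658-fold lower in ESC, Lox, which cross-links collagen, at least 538-fold, and Bgn, a matrix proteoglycan, 578-fold. Igf2, an imprinted growth factor, was 516-fold lower, from 14.01 ± 0.03 in MEF, and the matrix genes Mgp, Dcn, Thbs2 and Col1a1 were all lower by more than 8 on the log2 scale. The adjusted p of these genes, and of Dppa4, Ooep and Gldc, was at most 1.51e-17. In all, 4064 genes were higher and 3664 lower in ESC of the 10096 tested, with 1995 and 1900 of them at least 2-fold apart. When each array was scaled to its median in place of quantile normalization, 37.9% of the called genes were higher in ESC, against 52.6% here.

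All 32 measured genes of the pluripotency list were higher in ESC than in MEF, also when adjusted over the list alone, with a median log2 difference of 3.98 (camera adjusted p = 5.52e-14). All 32 measured fibroblast and mesenchyme genes were lower, with a median of -4.48, led by Lox, Bgn, Dcn and Col1a1 (2.07e-16). Of 17 epithelial genes 14 were higher and none lower (median 1.51, adjusted p = 0.000133), among them Spint1, a protease inhibitor, at least 49.9-fold, and the junction proteins Cldn6, Cldn4 and Cdh1, the last by 3.79 ± 0.11. Chromatin modifiers were higher in 20 of 25 cases, led by Dnmt3l, Dnmt3b (5.46 ± 0.10) and Tet1 (4.30 ± 0.18), and 1 of the others was lower when adjusted over the list alone. Cell cycle genes were higher in 22 of 25 cases (median 2.42, adjusted p = 1.53e-06), with Mcm5, a replication licensing factor, up by 4.00 ± 0.11. The largest change in that list went the other way: Ccnd2, cyclin D2, was 73.6-fold lower in ESC. Glycolysis genes were higher in 14 of 16 cases (median 1.76, adjusted p = 5.62e-05), led by the glucose transporter Slc2a3 at 53.0-fold. With genes undetected in one group taken at their bounds, the medians of the pluripotency, fibroblast and epithelial lists were 3.95, -4.44 and 1.39.

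Interferon response genes were lower in ESC in 16 of 19 cases and higher in 1 (median -1.61, adjusted p = 2.04e-05). Ifi27 was at least 84.8-fold lower, and B2m, the light chain of class I histocompatibility molecules, fell by 5.19 ± 0.13. Blood and macrophage markers were lower in 10 of 11 cases and higher in 1 (median -1.52, adjusted p = 0.00127, or adjusted p = 0.0713 with an estimated correlation). Lyz2, the macrophage lysozyme, stood at 9.61 ± 0.40 in MEF and was undetected in ESC, and the complement gene C1qb stood at 7.16 ± 0.22 in MEF and was also undetected in ESC. Targets of TGFb, BMP and WNT signalling were lower in 15 of 22 cases and higher in 5 (adjusted p = 0.00274), with Tgfbr2 down by 80.9-fold and Nodal up by at least 30.8-fold. Imprinted genes were lower in 10 of 18 cases and higher in 2 (adjusted p = 0.00344), led by Igf2, Dlk1 (181-fold) and Cdkn1c (152-fold). Apart from the macrophage markers, the calls named for ESC against MEF held with an estimated correlation. Over genes detected with p under 0.01 on all 12 arrays, the call for TGFb, BMP and WNT targets ended.

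The BAF complex list as a whole was not called in ESC against MEF (camera adjusted p = 0.84), with 8 of 22 subunits higher and 6 lower, though fry passed it (fry adjusted p = 0.00033). Smarca2, the ATPase that can take the place of Smarca4, stood at 10.69 ± 0.16 in MEF and 5.06 ± 0.29 in ESC, 49.5-fold lower. Smarce1 fell by 1.91 ± 0.12 and Arid1b by 1.63 ± 0.13, while Actl6a rose by 1.83 ± 0.16 and Smarca4 by 0.89 ± 0.11. Other probes of Smarca2 were detected on at most 2 of the 12 arrays. Under median scaling the Smarca4 call ended and the log2 differences of Bcl7a and Smarcb1, which were higher in ESC here, turned to -0.14 and -0.063.

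The iPS lines were compared with MEF to describe what reprogramming changed. Dppa5a was higher by 9.55 ± 0.11 in iPS4F and by 9.67 ± 0.11 in iPS6F, and Dnmt3l by 8.34 ± 0.11 and 8.32 ± 0.11. Upp1 was at least 256-fold and at least 284-fold higher, and Ooep, a protein of the egg's cortex, 227-fold and 269-fold. Ptn stood at -9.64 ± 0.10 in iPS4F and was at least 691-fold lower in iPS6F. Mgp, an inhibitor of calcification, stood at -8.34 ± 0.12 in iPS4F and was at least 359-fold lower in iPS6F. Lox was 289-fold and 435-fold lower, and Serpinf1, a secreted protein, stood at -8.13 ± 0.12 and -8.69 ± 0.12. The largest adjusted p among these genes was 2.27e-18. In iPS4F 4017 genes were higher and 3944 lower than in MEF, and in iPS6F 3960 and 3973, with 4054 and 4131 genes at least 2-fold apart.

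The gene groups called in ESC against MEF moved in the same direction in both iPS lines. Pluripotency genes were higher in 30 of 32 cases in iPS4F, with 1 lower, and in 31 of 32 in iPS6F, with medians of 4.17 and 4.28. All 32 fibroblast genes were lower in both lines, with medians of -4.58 and -4.36. Epithelial genes were higher in 16 of 17 cases in both (medians 2.59 and 2.48), glycolysis genes in 16 of 16, chromatin modifiers in 23 of 25 and cell cycle genes in 22 of 25. Interferon response genes were lower in 14 of 19 cases in iPS4F and 13 in iPS6F, and blood and macrophage markers in 10 of 11 in both (adjusted p = 0.0938 and 0.0983 with an estimated correlation). All of these lists passed with the preset correlation. With undetected genes at their bounds, the pluripotency medians were 4.06 and 4.17 and the fibroblast medians -4.51 and -4.25. Over genes detected with p under 0.01 on all 12 arrays, some calls ended in both lines. They were those for pluripotency and interferon response genes and for TGFb, BMP and WNT targets. That filter leaves out genes silent in any group, so the lists tested were not the same, and an ended call does not show a smaller change. Smarca2 was lower in iPS4F and iPS6F by 5.46 ± 0.16 and 5.63 ± 0.16.

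**Figure D2:**
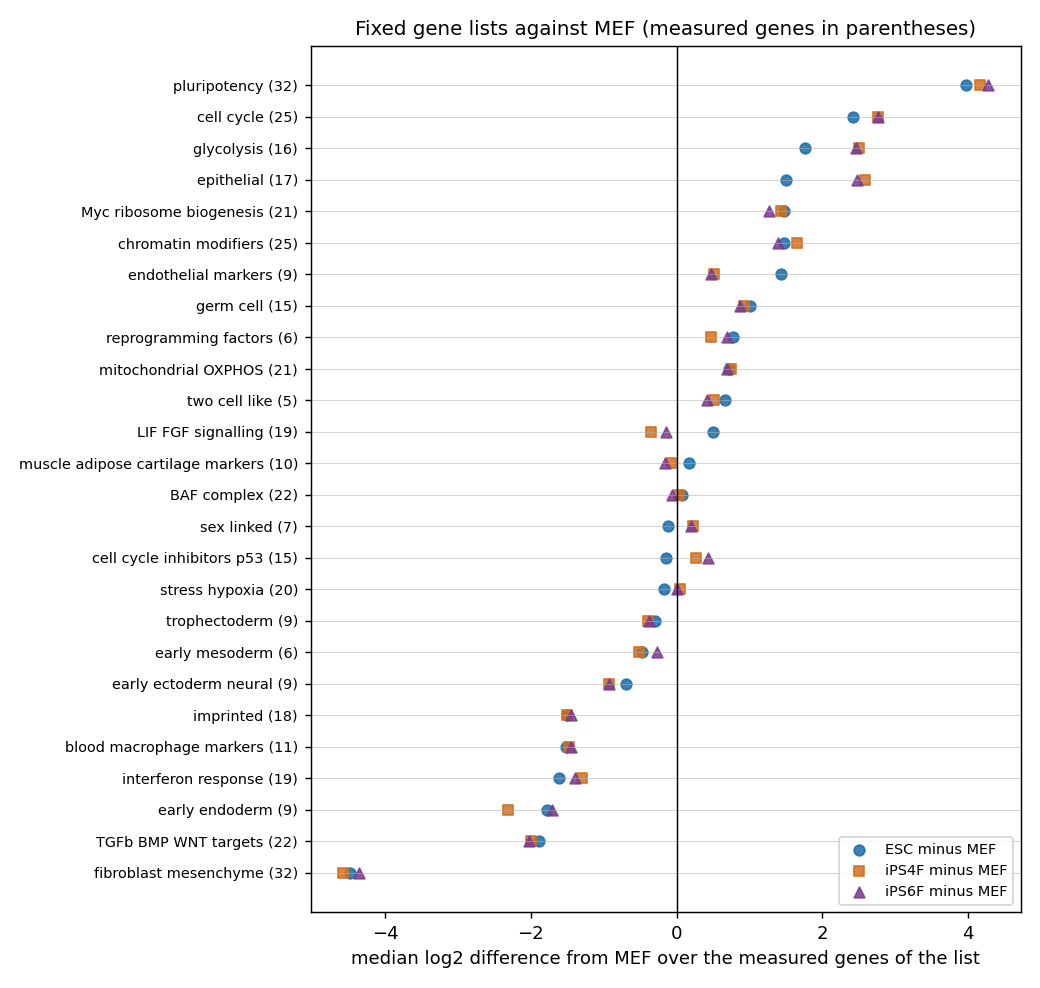
Median log2 difference from MEF over the measured genes of each of the 26 fixed lists, with the number of measured genes in parentheses, in ESC (circles), iPS4F (squares) and iPS6F (triangles). The pluripotency list lies at 3.98 to 4.28 and the fibroblast list at -4.58 to -4.36.

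How near each line came to ESC was measured over all genes. The root mean square log2 difference from the ESC mean was 0.539 ± 0.0129 in iPS4F and 0.572 ± 0.0121 in iPS6F (SD, n = 3), against 0.23 ± 0.0207 for an ESC array and the other ESC arrays and 1.54 ± 0.0107 for MEF. All 3 iPS6F arrays lay farther from ESC than all 3 iPS4F arrays, at an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. Over the 3895 genes at least 2-fold apart between ESC and MEF, iPS4F had covered 96.9 ± 0.256% of the MEF to ESC difference and iPS6F 97.7 ± 0.416%, again with no overlap between the arrays (exact p = 0.1). The distance thus placed iPS4F nearer to ESC, and the share placed iPS6F nearer. With median scaling the difference in distance turned to -0.153, but this scaling moved all genes in iPS4F more than in iPS6F. Centred on the median of all genes, it was -0.0277 (exact p = 0.2), while the share kept its direction (a difference of 1.88 percent).

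**Figure D3:**
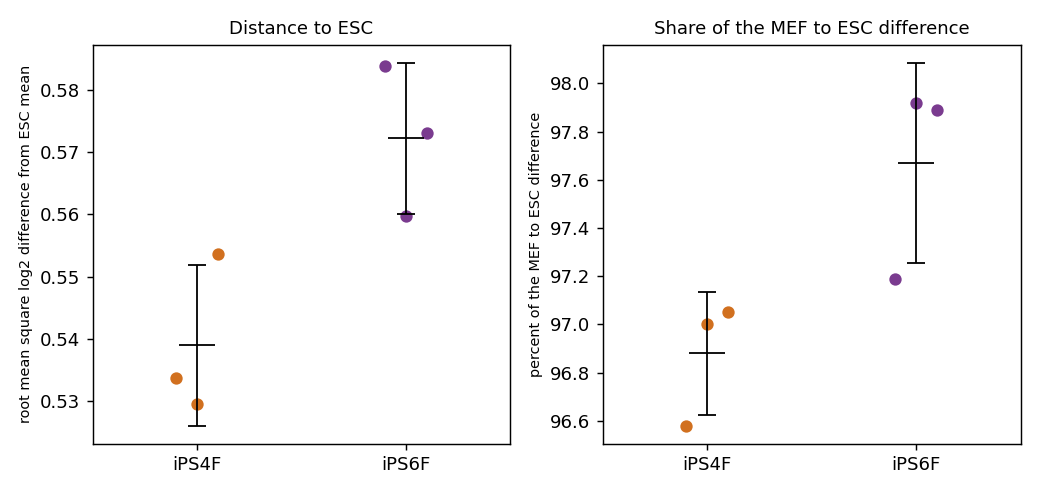
Left, root mean square log2 difference of each iPS array from the ESC mean over 10096 genes, and right, the percent of the MEF to ESC difference covered over 3895 genes (points are arrays, black bars mean and SD, n = 3, axes not starting at 0). The iPS6F arrays lie above the iPS4F arrays in both panels, which means farther from ESC at left and nearer to ESC at right. The mean difference of the left panel changes sign under median scaling.

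The iPS lines were next compared with ESC to find what still set them apart. Ipp was higher in iPS4F by 4.72 ± 0.13 and in iPS6F by 4.54 ± 0.13, and Emb, embigin, a cell surface protein, by 4.08 ± 0.13 and 3.78 ± 0.13. Eif2s3y, a translation factor gene on the Y chromosome, was at least 8.56-fold and at least 7.98-fold higher. Baiap2l1, which bends membranes, was 9.16-fold and 8.18-fold higher, and P4ha1, a collagen hydroxylase, by 2.70 ± 0.19 and 2.67 ± 0.19. Supt16, a subunit of the histone chaperone FACT, was lower by the largest margin, at -4.90 ± 0.19 and -4.55 ± 0.19. Tomm22, a subunit of the mitochondrial import pore, followed at -3.77 ± 0.12 and -3.87 ± 0.12, and Gbx2, a homeobox gene, at -2.96 ± 0.10 and -3.03 ± 0.10. Another detected probe of Supt16 gave -0.62 and -0.53, and another probe of Emb was undetected on all arrays. In iPS4F 1795 genes were higher and 2511 lower than in ESC, and 603 were at least 2-fold apart. In iPS6F 1799 were higher and 2826 lower, and 723 were at least 2-fold apart.

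Several other genes lay at the ends of these comparisons. Cldn4, a tight junction protein, was higher by 2.35 ± 0.10 in iPS4F and 2.30 ± 0.10 in iPS6F. Rnf114 was higher by 2.29 ± 0.16 and 2.53 ± 0.16, with another detected probe at 2.75 and 2.82. Ddit3, a transcription factor of the stress response, rose by 2.25 ± 0.13 and 2.53 ± 0.13. Apoa2, an apolipoprotein, was lower by -2.89 ± 0.14 and -2.87 ± 0.14, and Myo1f, a myosin, at least 6.39-fold and at least 6.22-fold lower. In iPS6F, Msmo1, an enzyme of cholesterol synthesis, stood at -2.86 ± 0.13 and Egr1, an immediate early transcription factor, at -2.84 ± 0.16. Casp9 was among the lowest in iPS4F at -2.65 ± 0.11, but 3 other probes of the gene were higher in iPS4F than in ESC, by 0.32 to 1.04, and its call ended when probes were averaged. When arrays were scaled to their median, 94.5% of the called genes were higher in iPS4F than in ESC, against 41.7% here, and 76.5% in iPS6F, against 38.9%.

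Genes of chromosome 8 were lower in iPS than in ESC more often than other genes. Of its 540 tested genes, 279 were lower in iPS4F than in ESC and 288 in iPS6F, 51.7% and 53.3%, against 23.5% and 26.7% of genes on the other autosomes. Their median log2 difference lay -0.33 from that of the other autosomal genes in iPS4F and -0.34 in iPS6F, while no other autosome lay beyond 0.07 in either direction. Other background corrections and scalings gave values between -0.153 (iPS4F, quantile normalization alone) and -0.497 (iPS6F, the authors' values). Set against the mean of both iPS lines and relative to the other autosomes, chromosome 8 genes stood 0.34 to 0.37 higher on the ESC arrays, and at -0.0233 to -0.0133 on the MEF arrays. Of the genes named here for iPS against ESC, Msmo1 and Brd7 lie on chromosome 8. Without the chromosome, an alternative added after the data were seen, 3965 genes passed the threshold in iPS4F and 4291 in iPS6F.

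**Figure D4:**
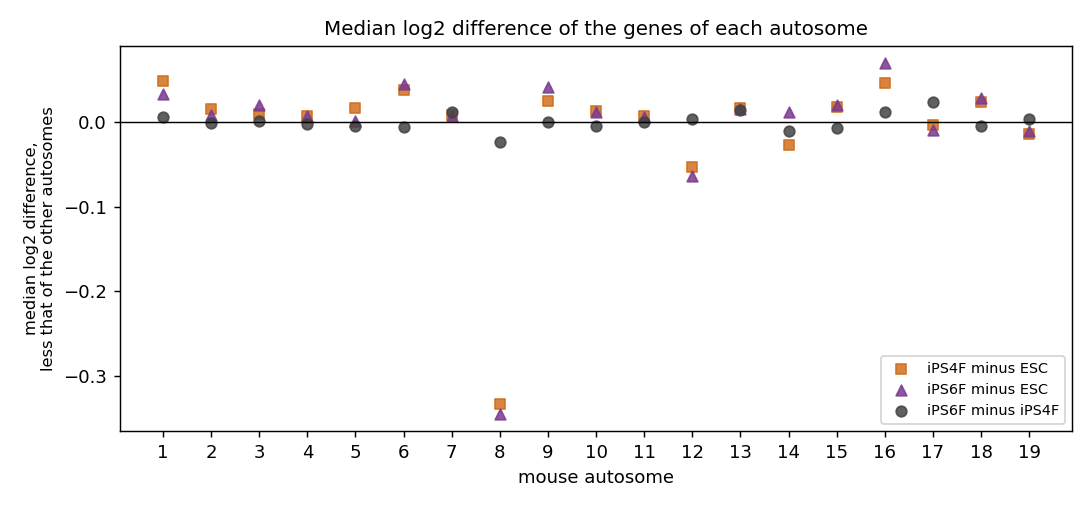
Median log2 difference of the tested genes of each mouse autosome, less the median of all other autosomal genes, for iPS4F minus ESC (squares), iPS6F minus ESC (triangles) and iPS6F minus iPS4F (circles). Chromosome 8 lies at -0.33 and -0.34 in the comparisons with ESC and at -0.02 between the iPS lines.

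The differences from ESC were largely shared by the lines. In the same direction in both lines, 3618 genes passed, 1451 higher and 2167 lower, and 7 passed in opposite directions. Independent lists of these sizes would share 1023. The log2 differences correlated at 0.934 across genes, against 0.501 from the shared ESC arrays alone in simulation, and their covariance was 0.266 against 0.0104. With 3 ESC arrays no split leaves 2 in each part, so what the shared arrays add was estimated by simulation alone. That simulation drew only the spread between arrays of a group. A feature common to all 3 ESC arrays would enter both differences in full, so the sharing cannot be laid to the iPS lines alone. At least 2-fold in both lines were 497 genes, 246 higher and 251 lower.

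Epithelial genes rose from ESC to iPS4F in 10 of 17 cases and to iPS6F in 11, with none lower (medians 1.03 and 0.67, adjusted p = 9.19e-07 and 3.43e-06). Cldn4, Grhl2, a regulator of epithelial junctions (2.03 ± 0.12 and 1.53 ± 0.12), and Krt18, a simple epithelial keratin (1.49 ± 0.13 and 1.39 ± 0.13), were among the leading genes of both lines, with Rab25 in iPS4F and Cldn6 in iPS6F. Inhibitors of the cell cycle and p53 targets rose in 11 and 12 of 15 cases with none lower (medians 0.64 and 0.58, adjusted p = 5.18e-06 and 3.43e-06). Cdkn2b, an inhibitor of Cdk4, was higher by 1.75 ± 0.11 and 1.71 ± 0.11, and Sesn2 by 1.07 ± 0.17 and 1.20 ± 0.17. Glycolysis genes rose in 12 and 10 of 16 cases with none lower (medians 0.56 and 0.45, adjusted p = 9.19e-07 and 8.56e-06). Pfkp, a phosphofructokinase, was higher by 1.70 ± 0.15 and 2.02 ± 0.15, and the hexokinase Hk1, undetected in ESC, was at least 2.08-fold and at least 2.55-fold higher. Adjusted over the list alone the counts were 11 and 11 for epithelial genes, 11 and 12 for inhibitors with 1 lower in iPS4F, and 12 and 10 for glycolysis. These 3 lists also passed with an estimated correlation, at adjusted p = 0.0366 and 0.0487, 0.0182 and 0.0149, and 0.0219 and 0.0387.

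Other groups passed camera with the preset correlation but not with an estimated one. Trophectoderm genes rose in 4 of 9 cases in both lines, with Id2 at least 1.98-fold and at least 2.04-fold higher and Tfap2c higher by 1.16 ± 0.09 and 1.13 ± 0.09 (adjusted p = 0.22 and 0.253 with an estimated correlation). Stress and hypoxia genes rose in 5 and 7 of 20 cases and fell in 2, led by Ddit3 and Ddit4 (adjusted p = 0.221 and 0.253 with an estimated correlation). In iPS4F, chromatin modifiers rose in 12 of 25 cases and fell in 3, with Ezh2 up by 1.47 ± 0.15, at adjusted p = 0.221 with an estimated correlation. Another detected Ezh2 probe gave -0.08 in iPS4F. Imprinted genes rose in 10 of 18 cases and fell in 2 in iPS4F, with Igf2 higher by 2.27 ± 0.16 and Ndn lower at -1.43 ± 0.14 (adjusted p = 0.0524 with an estimated correlation). In iPS6F the chromatin and imprinted lists were not called (camera adjusted p = 0.109 and 0.0654), and the difference between lines is given with the comparison of the lines.

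The pluripotency list was not called in either line against ESC (camera adjusted p = 0.493 and 0.292), with members moving both ways. Fry passed it in iPS6F (fry adjusted p = 0.00122) but not in iPS4F (0.184). In iPS4F 10 of 32 genes were higher and 11 lower, and in iPS6F 12 and 11. Otx2, a factor of primed pluripotency, was higher by 1.71 ± 0.13 in both lines, Fgf4 by 1.64 ± 0.10 and 2.19 ± 0.10, and Nr5a2 was lower in iPS4F at -1.70 ± 0.20. The fibroblast list was not called by camera either (0.292 and 0.596), with medians of -0.0085 and -0.07 and means of the other sign, 0.11 and 0.03. Fry passed this list in iPS4F (fry adjusted p = 0.0278) but not in iPS6F (0.417). Within it Fn1, fibronectin, was higher by 1.62 ± 0.14 and 1.92 ± 0.14, Bgn by 1.35 ± 0.16 in iPS4F, Sparc by 1.21 ± 0.11 in iPS6F, and Zeb1, a repressor of epithelial genes, lower at -1.12 ± 0.14 and -0.93 ± 0.14. Median scaling ended the Zeb1 calls.

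BAF subunits differed from ESC in both directions and the list was not called (camera adjusted p = 0.852 and 0.787). Fry passed the list in iPS6F (fry adjusted p = 0.0232) but not in iPS4F (0.0546). In iPS4F 3 of 22 were higher and 5 lower, and in iPS6F 5 and 7. Brd7, on chromosome 8, stood at -0.83 ± 0.11 and -0.78 ± 0.11, and Smarca4 at -0.81 ± 0.11 and -0.62 ± 0.11. Ss18 was higher by 0.77 ± 0.12 and 0.61 ± 0.12, and Smarcc1 by 0.63 ± 0.17 in iPS6F. Another detected Brd7 probe gave -0.03 and 0.00. Median scaling ended the calls of Brd7 and Smarca4 and turned the lower values of Phf10 and Smarce1 in iPS4F to 0.10 and 0.27.

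Transcripts of the sex chromosomes were compared with the sexes given in the labels. Xist, the RNA made by the inactive X chromosome of female cells, stood at 7.86 ± 0.25 in MEF, labelled male, and its brightest probe was undetected on every ESC and iPS array. The dimmest Xist probe in MEF (4.995) was detected on 2 iPS4F arrays and 1 iPS6F array, near the floor (means 4.323 and 4.412). Eif2s3y was undetected on all 3 ESC arrays (4.18 ± 0.09), stood at 5.77 ± 0.09 in MEF, and reached 7.56 ± 0.24 in iPS4F and 7.46 ± 0.24 in iPS6F. Both genes passed in ESC against MEF, with Xist at least 10.5-fold and Eif2s3y at least 2.46-fold lower in ESC.

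**Figure D5:**
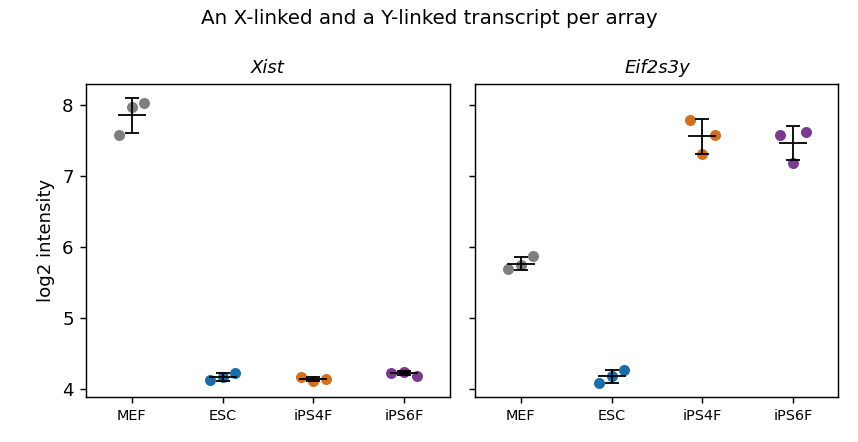
Log2 intensity of Xist and of Eif2s3y on each array, by group (points, 3 arrays per group), with the group mean and SD (black bars). Xist stands at 7.86 in MEF and near the floor elsewhere, and Eif2s3y is near the floor in ESC alone.

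The last comparison set iPS6F against iPS4F, to show what the lines made with and without the BAF subunits differed in. The labels do not say how many clones or cultures each group holds. Differences between clones therefore cannot be told apart from an effect of the added subunits. Rps3, a ribosomal protein, was higher in iPS6F by 2.11 ± 0.15, Maats1 by 1.48 ± 0.13, Hebp1, a heme-binding protein, by 1.18 ± 0.10, Cyp2b23 by 1.10 ± 0.14 and Eno2, an enolase, by 0.98 ± 0.12. Msmo1 was lower in iPS6F at -2.37 ± 0.13, Cep19 at -1.55 ± 0.12, Atf7ip at -1.43 ± 0.15, Acta2, smooth muscle actin, at -1.38 ± 0.13, Zfp869 at -1.27 ± 0.14, Slc40a1, the iron exporter, at -1.19 ± 0.11 and Igf2 at -1.13 ± 0.16. Another bright Rps3 probe gave -0.01, and other detected probes of Acta2 gave -0.69 to -0.22. Msmo1 lies on chromosome 8, whose genes differed from the other autosomes by -0.0244 between the lines, a small value outside random lists (-0.0185 to 0.0138). Of its genes 2.22% passed lower and 0.926% higher in iPS6F, against 0.641% and 0.38% on the other autosomes. In all, 117 of 10096 genes passed, 40 higher and 77 lower in iPS6F, and 14 were at least 2-fold apart, against 1300 genes at an unadjusted p under 0.05. The arrays of the lines did not overlap for 17.7% of genes, where chance gives 10% on average. All genes share the same arrays, so this share can stray from 10% by chance and carries no test.

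Leaving out 1 array moved the count of 117 to 48, 44 or 193 without iPS4F array 1, 2 or 3, and to 70, 72 or 58 without iPS6F array 1, 2 or 3. The count was 42 with median scaling, with 7.14% of the calls higher in iPS6F against 34.2% here, 47 on the authors' log2 values and 46 when the iPS arrays alone were fitted. Median scaling ended the calls of Hebp1 and Eno2, and the authors' values that of Igf2.

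Between the iPS lines, early endoderm genes were higher in iPS6F as a list (median 0.39, camera adjusted p = 3.4e-05, or adjusted p = 0.071 with an estimated correlation). Of its 9 genes, 2 passed singly, or 4 when adjusted over the list alone. Lama1, a laminin chain, was higher by 0.69 ± 0.13 and Col4a1, a collagen of basement membranes on chromosome 8, by 0.49 ± 0.10. The pluripotency list (median 0.08, adjusted p = 0.0129) and the 6 factors (median 0.23, adjusted p = 0.0215) also passed upwards, each at adjusted p = 0.129 with an estimated correlation. Both calls ended under median scaling (medians -0.28 and -0.06, against -0.29 for all genes), on the authors' values, and without iPS4F array 2 or iPS6F array 1 (adjusted p = 0.0594 to 0.0967 without an array). Leaving out iPS6F array 3 also ended the call of the factors (0.062), and detection under 0.01 on all 12 arrays that of the pluripotency list (0.159). Of the pluripotency genes Fgf4 alone passed, higher by 0.56 ± 0.10, and of the factors none passed. None of the 22 BAF subunits passed, and the list was not called (camera adjusted p = 0.968, fry adjusted p = 0.678). Among single members of other lists, Lefty1, an inhibitor of Nodal, stood at -1.05 ± 0.12, Dusp6, which turns off ERK, at -0.81 ± 0.12 and the glycolytic enzyme Pkm at -0.63 ± 0.11. The chromatin and imprinted lists were not called between the lines (camera adjusted p = 0.45 and 0.226), but fry passed the imprinted list downwards (fry adjusted p = 0.00646, and 0.258 for chromatin).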

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

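The test of female cells among the MEF was chosen after the results were seen, and the tests of expression kept from fibroblasts and of a shared genetic background were separated into genes higher and lower in iPS, the latter with another choice of genes, after their joint results were seen.

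Genes whose change from MEF differed between the iPS lines drew attention because the difference itself passed a test. These were 117 genes past an adjusted p of 0.05, of which 14 were at least 2-fold apart, among them Rps3, Maats1, Msmo1 and Cep19. Another bright probe of Rps3 showed no such difference. The test between the lines cannot tell the added factors from differences between clones. On the authors' log2 values 117 of the 117 genes kept their direction and 39 passed. Those values come from the same arrays on which the genes were chosen, so the kept direction is no separate support.

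Other splits of the 6 arrays of each comparison into 3 and 3 were counted. For each of ESC against MEF (7728 genes), iPS4F against MEF (7961), iPS6F against MEF (7933), iPS4F against ESC (4306), iPS6F against ESC (4625) and iPS6F against iPS4F (117), 1 of the 10 splits, the real one, gave as many genes, and the highest other gave 0. With 10 splits a share under 0.05 cannot be reached. Each other split also mixes arrays of both groups, which puts the group difference into the spread. Few or no calls were therefore bound to follow where the groups differ widely, so the 0 is no measure of chance.

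Probes without a gene symbol, which the gene tests of the report left out and only the alternative that counts all probes used, also changed. Of 2269 such probes that passed the detection filter, 633 were past the threshold and at least 2-fold apart between ESC and MEF, 176 between iPS4F and ESC, 194 between iPS6F and ESC, and 2 between iPS6F and iPS4F.

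Xist was detected in MEF labelled male, and the Y-linked Eif2s3y was undetected in ESC labelled as a mix of female and male. Cross-hybridization of a single Xist probe was argued against by 3 other Xist probes, of 4 in all, that were detected on all 3 MEF arrays. ESC with 2 active X chromosomes were argued against by 335 X-linked genes, whose median, iPS minus ESC, lay 0.018 above that of autosomal genes in iPS4F and 0.00842 in iPS6F, where random lists gave -0.0418 to 0.0436 in iPS4F. Female cells among the MEF may account for the Xist signal. Eif2s3y was lower in MEF than in iPS6F by 1.696 (adjusted p = 5.52e-09) and than in iPS4F by 1.796. The level of this gene cannot decide it, since 4017 of 10096 genes were higher in iPS4F than in MEF and 3960 in iPS6F, whatever the sex. For the missing Eif2s3y in ESC, sex, which the labels name as a difference between ESC and MEF, stays open apart from cells with 2 active X chromosomes. A Y chromosome lost in culture stays open too. Beyond the X-linked genes, neither was tested.

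The 497 genes at least 2-fold apart from ESC in the same direction in both iPS lines were examined for their source. For the higher ones, a genetic background shared by iPS and MEF cannot be decided. Of 181 detected in MEF and iPS, 30.9% had a MEF level nearer iPS than ESC, below the 34.3 to 48.1% of random lists. But those lists drew on genes higher in iPS by any amount, where a MEF level barely above ESC is already nearer iPS. A lower share among genes 2-fold apart was thus to be foreseen. For the lower genes this background cannot be told apart either. There 51.4% had a MEF level nearer iPS, inside the 48.2 to 59.8% of random lists drawn likewise, while the share also lower in MEF lay above them. Expression kept from fibroblasts was argued against as a source of most of the 246 higher genes. Of these, 33.3% were also higher in MEF, inside the 29.3 to 41.1% of random lists, and 106 were lower in MEF than in ESC. For the 82 also higher in MEF a share over the whole set cannot decide. Kept expression may account for some of the 251 lower genes, of which 64.1% were also lower in MEF (random lists 37.5 to 49%, and 62.1% without chromosome 8), but features of these ESC cultures or error in the shared ESC arrays would give the same. A sequence difference under single probes cannot be told apart. Another probe of 202 genes showed a median of 0.503 of the main probe's change, against 0.653 in size-matched genes (permutation p = 0.04). The median lay just above the bound set beforehand, which was to count against this cause. Its bootstrap range (0.391 to 0.584), which that rule did not name, lay on both sides of the bound.

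Chromosome 8 genes were lower in both iPS lines than in ESC, with medians -0.344 and -0.333 from the other autosomes over 540 genes, where random lists gave -0.0573 to 0.0234 in iPS6F, and with -0.153 to -0.497 under other background corrections and scalings, so the size gives no copy number. A copy lost in both iPS lines was argued against, since against MEF the medians were 0.0215 in iPS4F and -0.0129 in iPS6F, inside random lists. An extra copy in most ESC may account for the pattern: in ESC minus MEF the chromosome lay 0.341 above the others, where random lists gave -0.0568 to 0.141. A change in only part of the chromosome also stays open, since in iPS6F minus ESC the first of 10 consecutive segments lay at -0.0104 (bootstrap -0.111 to 0.104) and the others at -0.254 to -0.507, and in iPS4F minus ESC at -0.0452 and -0.218 to -0.54. No other measure of copy number was used here, and the extra copy remains a hypothesis.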

How the results depend on the processing

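Leaving out chromosome 8, centring the distance and leaving out arrays in the list tests were alternatives chosen after the data were seen; the other tests were planned.

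Counts of genes, distances and shares were recomputed under 361 alternatives. Of these, 310 stayed within 1.5 times the count or, for distances and shares, only kept their sign, 49 moved and 2 reversed. Some could not change, since a distance uses no MEF array and leaving out a MEF array leaves it as it was. Calls of gene lists held in 1111 of 1160 alternatives and ended in 49, and lists not called stayed so in 1961 of 2044. Calls of named genes held in 12376 of 12828, ended in 441 and reversed in 11. For each comparison, values below are in the order ESC minus MEF, iPS4F minus MEF, iPS6F minus MEF, iPS4F minus ESC, iPS6F minus ESC and iPS6F minus iPS4F. Counts past the adjusted p of the first 5 stayed within 1.5 times with quantile normalization alone, normexp with offset 50, the authors' values, no filter, the mean of probes, the replicate block and each array left out.

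Without background correction, genes at least 2-fold apart numbered 1971, 2004, 2030, 125, 166 and 3, and with normexp at offset 50 they numbered 2542, 2589, 2638, 213, 271 and 6. Both leave more background or offset in the values, which by construction shrinks folds, and the authors' values, with 6107 for iPS4F minus MEF, 1878 and 2118 for the iPS lines minus ESC and 37 for iPS6F minus iPS4F, went the other way. Detection under 0.01 on all 12 arrays tested 5982 genes and so called fewer: 4774, 4779 and 4813 against MEF, with 2353, 2443, 2495, 358 and 466 at least 2-fold apart. Counting all 17563 probes gave 12429, 13303, 13343, 7289 and 7831, with 5893, 6415, 6570, 1171 and 1390 at least 2-fold apart, and 6127 shared by both iPS lines against ESC, since genes have several probes and 2269 of the probes have no symbol.

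Median scaling gave 1480 genes at least 2-fold apart in iPS4F minus ESC, 2098 past the threshold in iPS6F minus ESC, 42 and, at least 2-fold, 30 in iPS6F minus iPS4F, and 1785 shared by both iPS lines. It reversed the distance to ESC, with iPS6F minus iPS4F at -0.153 (exact p = 0.1), where other normalizations gave 0.0185 to 0.0582. With each array's differences centred on their median it was -0.0277 under median scaling (exact p = 0.2) and 0.0312 otherwise, so the shift of all genes made up most of the change. Median scaling moved the median of all genes to 0.387 in iPS4F minus ESC, -0.292 in iPS6F minus iPS4F, 0.241 in iPS4F minus MEF and -0.141 in ESC minus MEF. The authors' values moved it to 0.149 in ESC minus MEF and -0.134 in iPS6F minus ESC. Under median scaling the higher share of genes at least 2-fold apart became 35.5% (from 51.2%), 58.5% (47.8%), 43.9% (47.5%), 96.3% (49.9%), 79.6% (46.1%) and 6.67% (28.6%). Apart from the distance, the cause was not tested.

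Genes past the threshold in iPS6F minus iPS4F numbered 47 on the authors' values, 46 when the iPS arrays alone were fitted, 94 with the replicate block and 86 without chromosome 8. A test against a fold of 1.5 (treat) gave 8. Leaving out 1 array gave 44 (iPS4F array 2) to 193 (iPS4F array 3). The cause was not tested. The block leaves overlap at 3622. It left the share difference at 0.789, but it enters only the choice of genes for the share, so this value says nothing on pairing. No slide block was run, since no slide is given.

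Reversed under median scaling were Bcl7a (-0.14), Smarcb1 (-0.063) and Ddx3x (-0.10) in ESC minus MEF and Phf10 (0.10), Smarce1 (0.27), Dab2 (0.027), Gata6 (0.12) and Ccnd1 (0.017) in iPS4F minus ESC. In iPS4F minus ESC these 5 stayed below the median of all genes under that scaling, and Smarcb1 and Ddx3x stayed above it in ESC minus MEF. Averaging the probes of a gene reversed Kdm2b (0.11 in iPS4F and 0.19 in iPS6F minus ESC) and Pbrm1 (0.019 in iPS6F minus ESC). Signal over background limits the folds of dim genes, and arrays detected 14107 to 17741 probes.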

Other observations

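No test in this part was chosen after the result was seen, and the genes are those of the fixed rule.

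Developmental groups were not called by camera between MEF and ESC, though their medians and single members differed. Early endoderm genes were lower in ESC in 6 of 9 cases and higher in 2 (median -1.78, camera adjusted p = 0.12), led by Pdgfra at -5.13 ± 0.12. Early mesoderm genes went both ways, with Nodal at least 30.8-fold higher and Bmp4 at -2.16 ± 0.12 (adjusted p = 0.646). Their median was -0.47 and their mean 0.23. Neural genes were lower in 6 of 9 cases, led by Ncam1 at -4.08 ± 0.17, with Otx2 higher by 3.53 ± 0.13 (adjusted p = 0.147). Trophectoderm genes were higher in 3 and lower in 5 of 9 cases, led by Tfap2c (adjusted p = 0.84), with a median of -0.29 and a mean of 0.16. Genes of the 2-cell stage, Zscan4c among them, were higher in 5 of 5 cases (adjusted p = 0.0662).

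Germ cell genes were higher in ESC than in MEF in 12 of 15 cases, with Rhox5 at 98.6-fold (adjusted p = 0.00222), and passed in both iPS lines with 11 of 15. Genes of Myc and ribosome biogenesis were higher in 18 of 21 cases in ESC, led by Gnl3 at 2.98 ± 0.13, and in 17 in both iPS lines (adjusted p = 0.000453, 0.000721 and 0.000903). Mitochondrial respiration genes were higher in 16, 15 and 15 of 21 cases, led in ESC by Cyc1 at 1.71 ± 0.12 (adjusted p = 0.00344, 0.00506 and 0.00269). Imprinted genes were lower in both iPS lines than in MEF in 12 of 18 cases (adjusted p = 0.0222 and 0.0149, in iPS4F adjusted p = 0.0545 with an estimated correlation), and TGFb, BMP and WNT targets in 16 of 22. The 6 factors as a list (adjusted p = 0.078), cell cycle inhibitors (0.248), LIF and FGF signalling (0.615), stress and hypoxia (0.84), endothelial (0.117), muscle, fat and cartilage (0.84) and sex-linked genes (0.41) were not called in ESC against MEF.

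Against ESC, interferon response genes were higher in iPS4F in 8 of 19 cases and lower in 1 (camera adjusted p = 0.02, or adjusted p = 0.0856 with an estimated correlation), and in iPS6F in 6 with 1 lower (0.106). Sex-linked genes were higher in 4 of 7 cases in iPS4F, led by Eif2s3y (adjusted p = 0.0325, or adjusted p = 0.135 with an estimated correlation), and in 2 in iPS6F (0.222). Neither list was called between the lines (0.724 and 0.356). Early endoderm genes were lower in iPS4F in 5 of 9 cases (adjusted p = 0.0614) and in iPS6F in 1, with Lama1 at -1.54 ± 0.13 and -0.85 ± 0.13. Targets of TGFb, BMP and WNT were lower in 5 and 10 of 22 cases, with Id1 at -1.95 ± 0.13 and -1.52 ± 0.13 (adjusted p = 0.296 and 0.312). The lists of cell cycle (0.201 and 0.283), Myc and ribosome biogenesis (0.811 and 0.619), mitochondrial respiration (0.855 and 0.759), germ cell (0.243 and 0.358), LIF and FGF signalling (0.347 and 0.336) and blood and macrophage markers (0.47 and 0.383) were not called. Besides the 3 lists named for iPS6F against iPS4F in the report, camera called no list between the iPS lines, while fry also passed the imprinted list (median -0.12, fry adjusted p = 0.00646) and Myc and ribosome biogenesis (median -0.03, 0.0206).

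Array numbers were checked as a possible pairing. Between groups, 3 of 18 pairs of arrays with the same number correlated above 0.1 in their residuals, with values from -0.176 to 0.14, and 6 of 12 arrays correlated best with an array of their own number.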
